A study of Homo sapiens with 8 samples.

How the data were processed

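Total RNA from mononuclear cells of human bone marrow was hybridised, per the labels, to one-colour (Cy3) Arraystar lncRNA V3 arrays made by Agilent, with 6 arrays labelled AML and 2 labelled as non-leukemia controls. The deposited scanner files hold spot intensity values that the authors obtained with Agilent Feature Extraction 11.0.1.1, per the file headers; the processed signal had been background-subtracted and spatially detrended. The deposited series table holds log2 values that the authors had made; each column correlates best with the scanner values of its own array, and the columns nearly coincide once sorted. They were therefore taken as quantile normalized, which no label states. The table was used only as an alternative.

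Values were log2 of the processed signal minus each array's 75th percentile over probes other than controls. Control spots, 60 negative-control probes and spots flagged as outliers were left out, saturated spots were kept, and spots of one probe were averaged. A probe was tested if it was well above background, in most of its spots, on at least 2 of 8 arrays. A further 14 probes without an unflagged value in a group were dropped. Groups were compared with lmFit and eBayes of limma 3.58.1 in R 4.3.3, two-sided, with Benjamini-Hochberg adjustment over all tested probes. Single measures per array were compared by exact two-sided permutation tests, and with the slide as a block by permuting labels within slides, a form of that planned block chosen after seeing the data. Figures were drawn with matplotlib 3.10.9.

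The test, the groups, the gene lists, the rule for named genes and the first set of alternatives were fixed before the data were examined. That rule would have named the protein-coding genes and the long non-coding RNAs with the largest called rise and fall, a fixed panel of marrow genes, and members of called gene lists. It could not be followed. The arrays' own probes carry only manufacturer identifiers, and of all probes only 20 (0.0339%) carry a RefSeq accession, each printed in 10 spots. All 20 matched a symbol in the RefSeq table of assembly GRCh38.p14 that was used for names, and 19 passed the filter. Of 34 gene lists, 3 held 1 of the named genes and the rest none, so the tests of lists, the separate counts of protein-coding and long non-coding probes, the panel and the cell type markers are not analysed here. Of the 20 genes, 17 are described instead, a choice made after their values were seen, and 3 are not reported here. Unnamed probes are only counted.

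Arrays of one group were compared over 24165 probes well above background on all 8 arrays, by the share whose difference exceeded 1.96 times the scanner software's own error. How to merge arrays that are near copies was decided after seeing the data, and 4 rules were tried. The first compared the spread of 11209 bright probes with the noise between repeat spots of bright named probes, the second with that of all named probes; each merged 2 AML pairs and left the control pair apart, at 4 against 2 samples. The third merged pairs with under 1% of probes beyond the limit, a value chosen from a gap in the data, and left 4 against 1. The fourth used the nominal 5% of the error model, left 3 against 1, and sets n, the means and the SDs given here because it claims the fewest independent samples. Call counts are given under each.

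The files show 2 scans, taken as slides. Slide 1 held 4 AML arrays and 1 control array, and slide 2 held 2 AML arrays and 1 control array. Other alternatives were normexp background correction with an offset of 50, other scalings and filters, the authors' values, other variance models, slide and replicate blocks, and leaving out each array. Normexp used median spot signals, because mean signals were not among the columns used. The estimate of array weights stopped before it converged, so its counts carry that limit.

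The test was run on simulated data with the real probes' means and spreads and 200 changed probes among 36702. In every design the noise between copies was that of the pairs under 1%. The spread between samples was that of the AML samples with those pairs merged. The further pairs of the 5% rule differed more, with a spread of 0.078 to 0.083 against 0.047 to 0.061, so its simulated copies were closer than those pairs. Each probe was drawn independently, whereas probes of a real sample can move together, so real counts without a group difference could vary more widely. The adjustment is stricter with so few changed probes than where many change, so the shares recovered do not apply to the real fits. With 8 separate samples, 16.4% of changes of 1, 50.7% of changes of 2 and 72.7% of changes of 3 on the log2 scale were recovered, with 3 calls among unchanged probes. With no changed probe, 20 simulations of 8 separate samples gave a median of 0 calls. Near-copies as in the 5% rule gave a median of 3438 calls (range 3235 to 3633) in a fit to 8 arrays, and near-copies as in the 1% rule gave 1048. The merged fits gave a median of 0 calls but recovered 0 of the 200 changed probes, so a count of 0 after merging does not show that nothing changed.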

Results

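RNA levels were measured in mononuclear cells of human bone marrow from 2 groups, acute myeloid leukemia (AML, a cancer of immature myeloid blood cells) and a non-leukemia control group. The labels list 6 AML and 2 non-leukemia samples, each with its own one-colour array, which carries probes for messenger RNAs and for long non-coding RNAs. Of 58965 probes, between 28178 and 34442 gave a signal well above background on an array. The number of arrays limits the precision of every value. The question was which RNAs differ in level between AML and control marrow. Only 20 probes carried an accession that gives a gene name, so the genes below come from those 20, and the other probes are counted without names.

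Most genes with a named probe gave more signal in AML than in control marrow. PRMT1, an enzyme that methylates arginines in histones and other proteins, stood at a scaled log2 signal of 5.82 ± 0.23 (SD, n = 3 merged AML samples) against 3.29 in the single merged control sample, a 5.74-fold difference. EIF3D, a subunit of a translation initiation factor, was 4.27-fold higher, at 7.75 ± 0.28 (SD, n = 3) against 5.66. COX4I1, a subunit of cytochrome c oxidase in the mitochondrial respiratory chain, was 2.84-fold higher, at 8.73 ± 0.25 (SD, n = 3) against 7.23. Each of these lay above the control in 3 of 3 merged AML samples. None passed limma's test with the arrays merged in this way, where PRMT1 had an adjusted p of 0.085. That fit has 1 control sample, assumed to vary like the AML samples, so a missed threshold in it does not show that a gene is unchanged. Within slide 1 the PRMT1 difference was 2.54 and within slide 2 it was 2.39 on the log2 scale. Each array on slide 2 is a near copy of an array on slide 1, as described below, so slide 2 is not an independent repeat. In the planned limma fit to all 8 arrays the adjusted p was 3.05e-05 for PRMT1, 9.12e-05 for EIF3D and 0.000327 for COX4I1.

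The arrays were not all distinguishable, which is why samples were merged. In 3 pairs of arrays, of which 2 were AML and 1 was the control pair, at most 0.675% of 24165 probes differed by more than 1.96 times the error that the scanner software gives. The software's error model itself puts 5% of probes beyond that limit. A further 2 AML pairs had 4.65% and 4.96% of probes beyond it. Of the other 11 pairs of one group, 2 AML pairs had 13.2% and 14.1%, and the rest had between 39.6% and 48.3%. In those 2 pairs 0.28% and 0.29% of bright probes differed by more than 2-fold, against 10.6% to 13.9% in the rest. Arrays under the 5% limit differed by no more than the scanner software's error allows and were counted as 1 sample, which left 3 AML samples and 1 control sample. The pairs at 13.2% and 14.1% join the AML array left single to the 2 arrays of a merged pair. The count of 3 may therefore overstate how many AML samples are separate. In 3 of the 5 merged pairs the spread of the differences was 1.16, 1.67 and 2.26 times the noise between repeat spots of one array, so their merging rests on the scanner's error alone. The limit was chosen after seeing the data. Nothing in the labels says whether the arrays came from separate donors, so p-values measure only the spread between these samples, which may be technical.

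**Figure D1:**
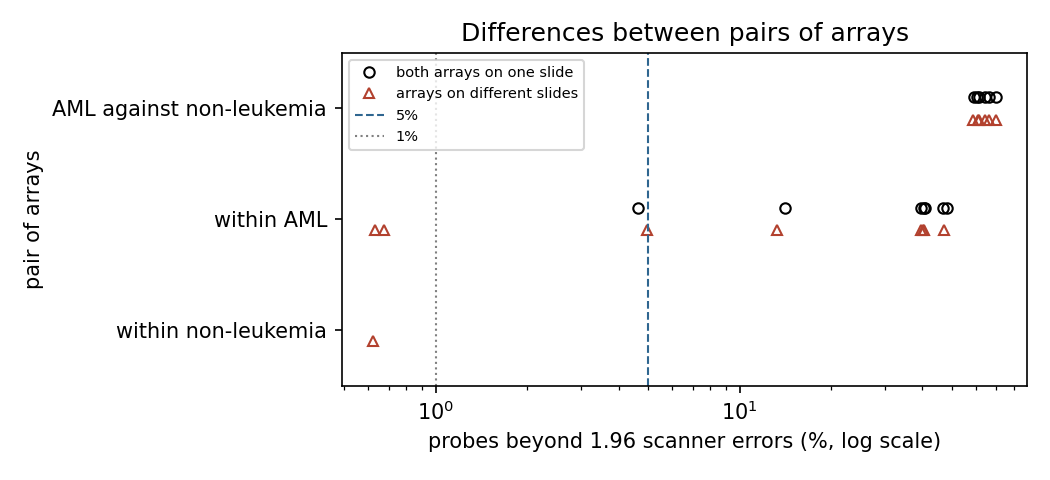
Percent of probes that differ by more than 1.96 scanner errors (horizontal axis, log scale) for each pair of arrays within AML, within non-leukemia and between the groups; circles are pairs on one slide, triangles pairs on different slides, and vertical lines mark 1% and 5%. The 3 pairs under 1% all span both slides, and pairs between the groups lie between 58.5% and 70.0%.

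RPS18, a protein of the small ribosomal subunit, was higher by 1.21 on the log2 scale (SE 0.26), and RACK1, a scaffold protein bound to the ribosome, by 1.07 (SE 0.27). RPLP1, a protein of the large subunit's stalk, was higher by 0.56 (SE 0.26), with the 3 AML samples at 10.80 ± 0.07 (SD, n = 3) against 10.24. The RPL10 probe gave 0.32 (SE 0.47), above the control in 2 of the 3 AML samples, and between 0.06 and 0.52 when a merged AML sample was left out. Its signal was weak, at -0.05 in AML and -0.37 in the control, where the RPS18 probe stood at 10.83 in AML. H3-3A, which encodes histone variant H3.3, was higher by 1.33 (SE 0.42), and ODC1, which catalyses the first step of polyamine synthesis, by 0.87 (SE 0.27). With the arrays merged, limma's adjusted p was 0.113 for RPS18, 0.129 for RACK1, 0.160 for ODC1, 0.162 for H3-3A, 0.248 for RPLP1 and 0.657 for RPL10. In the fit to 8 arrays RPS18, RACK1, RPLP1, H3-3A and ODC1 passed the threshold and RPL10 did not (adjusted p = 0.212), though it did with array weights (0.60, adjusted p = 0.012) and with group-specific variances (adjusted p = 0.040). Under quantile normalization of the 8 arrays RPLP1 fell to 0.32 and no longer passed (adjusted p = 0.058).

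ACTG1, the cytoplasmic gamma-actin gene, was higher by 0.63 (SE 0.29), whereas ACTB, the beta-actin gene, differed by 0.04 (SE 0.30). Both depended on the scaling of the 8 arrays: under quantile normalization ACTG1 went from 0.58 to 0.18 (limma adjusted p = 0.384), and ACTB from 0.07 to -0.30 (adjusted p = 0.047). PFN1, which encodes the actin-binding protein profilin, gave -0.45 (SE 0.49), and -0.70 under quantile normalization of the 8 arrays (adjusted p = 0.047). Its merged AML samples ranged from 9.26 to 10.20 against 10.07 in the control, with 1 of 3 above it. DYNLL1, a light chain of dynein, was higher by 0.83 (SE 0.47). MTX1, a protein of mitochondrial import, stood at 4.97 ± 0.35 (SD, n = 3) against 5.79 in the control, with 0 of 3 AML samples above it. Its adjusted p was 0.250 with arrays merged and 0.040 in the fit to 8 arrays. That call was lost with the slide as a block (-0.74, adjusted p = 0.063), under median scaling (-0.57, adjusted p = 0.096), without a filter and when any of 5 of the 8 arrays was left out. The call of DYNLL1 in limma's fit to 8 arrays (adjusted p = 0.044) was also lost with the slide as a block (adjusted p = 0.071). It was lost as well under the percentile of detected probes (0.073), without a filter (0.072) and when any of 7 of the 8 arrays was left out. Among these, leaving out an AML array gave an adjusted p of 0.053 to 0.062. Without the remaining AML array, the highest at 9.13, the change was 0.56 and the call was kept (adjusted p = 0.003). GRM4, a glutamate receptor gene, was well above background on 0 AML arrays and on only 1 of the 2 control arrays.

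**Figure D2:**
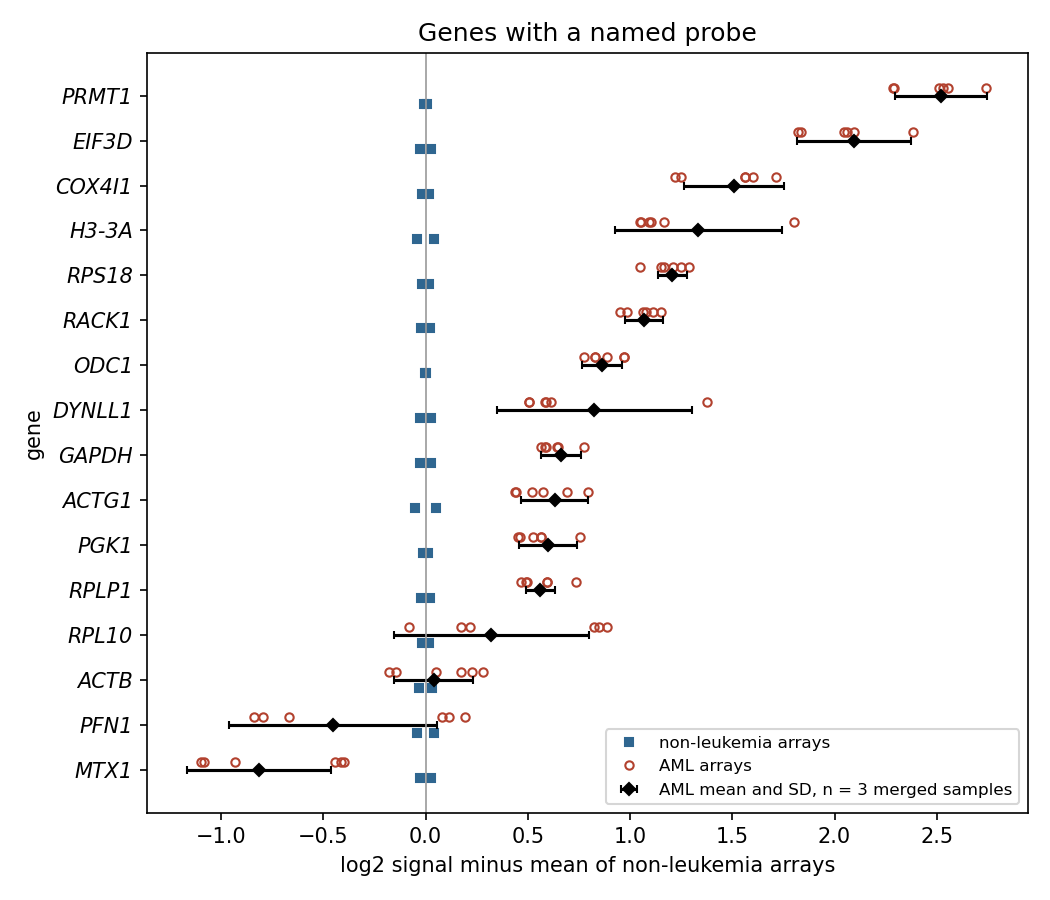
Log2 signal of each array minus the mean of the 2 non-leukemia arrays (horizontal axis) for 16 tested genes with a named probe; circles are AML arrays, squares are non-leukemia arrays, and diamonds with bars are the mean and SD of the 3 merged AML samples. PRMT1 lies farthest to the right, at 2.52, and MTX1 farthest to the left, at -0.81.

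The glycolytic genes GAPDH and PGK1 were measured by more than 1 probe, and the probes gave different changes. The named GAPDH probe was higher in AML by 0.66 (SE 0.27), and control probes at the 3' and 5' ends of the transcript by 0.35 and 0.80. Over 8 arrays the named probe went from 0.63 to 0.23 under quantile normalization and no longer passed the threshold (adjusted p = 0.209). The named PGK1 probe was higher by 0.60 (SE 0.28), its 5' end probe by 0.42, and its 3' end probe gave -0.06. The named PGK1 probe had the weakest signal of these, at 2.13 in AML against 4.64 for the 5' and 8.36 for the 3' end probe. The gap between the 3' and 5' probes, which depends on RNA integrity among other things, was smaller in AML than in the control, by 0.38 for GAPDH and by 0.47 for PGK1 on the log2 scale over 8 arrays. Each gap had an exact two-sided permutation p of 0.0714, the smallest that 28 assignments allow, and 0.107 after Benjamini-Hochberg adjustment over 3 measures. That test treats the 8 arrays as separate samples. With merged samples the exact p was 0.5 for each gap, the smallest that 4 assignments allow, and with labels permuted only within slides it was 0.133, the smallest that 15 assignments allow. Within slide 1 the GAPDH difference was -0.38 and within slide 2 it was -0.37, and the PGK1 differences were -0.48 and -0.49. The slide 2 arrays are near copies of slide 1 arrays, so the slides are not independent repeats.

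**Figure D3:**
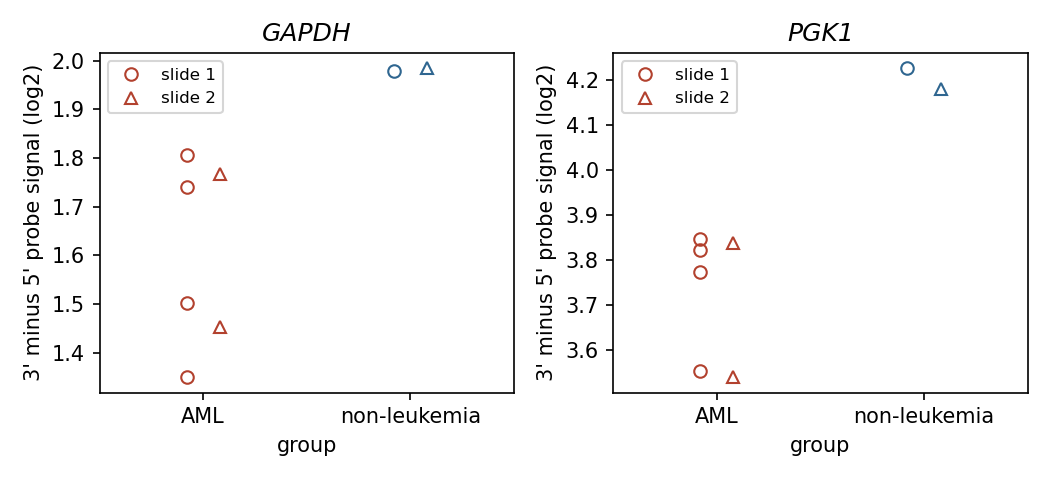
Log2 signal of the 3' end probe minus that of the 5' end probe of GAPDH (left) and PGK1 (right) on each array, by group; circles are slide 1 and triangles slide 2. The AML arrays average 1.60 for GAPDH and 3.73 for PGK1, and the non-leukemia arrays 1.98 and 4.20.

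Across all 36812 probes tested, the planned limma fit to 8 arrays called 7646 probes higher and 10588 lower in AML at an adjusted p under 0.05. In the same fit without blocks, simulated data with no difference between groups gave a median of 3438 calls with near copies as in the 5% rule, and of 1048 with near copies as in the 1% rule. Those simulated probes varied independently, and some simulated copies under the 5% rule were closer than the real pairs. The counts therefore do not measure what real arrays without a difference would give. With the slide as a block the fit to the real arrays called 6836 higher and 9362 lower. With arrays under the 5% limit merged, limma called 0 of 36795 probes, and 10131 had an unadjusted p under 0.05, where 1840 would be given by chance. Merging only the pairs under 1%, a narrower limit also chosen after seeing the data, left 4 AML samples and 1 control sample and called 2065 probes higher and 991 lower. PRMT1, EIF3D, COX4I1 and RPS18 were the named genes called in that fit, with adjusted p between 0.023 and 0.045. The spread in it comes from the AML samples alone, and the 1 control sample is assumed to vary like them. Merging by the noise between repeat spots, under both versions tried, left 4 AML samples and 2 control samples and called 6684 probes higher and 8664 lower. It kept 11 of the 13 named genes called from 8 arrays, all but MTX1 and DYNLL1, but counts the 2 control arrays as separate samples. The split between higher and lower calls also depended on scaling, since 41.9% of calls were higher in AML under the 75th percentile and 52.9% under the median. Each fit that follows has 1 control array or sample, assumed to vary like the AML ones. Where the merged sample of 3 arrays is left out, the 2 AML samples that remain are those joined by the pairs at 13.2% and 14.1%. They lie close to each other, so the spread in that fit is small and its calls do not measure a hidden difference. Slide 1 alone gave 2023 probes higher and 929 lower, and slide 2 alone gave 0, with 4487 at an unadjusted p under 0.05. Without 1 of the control arrays the fit to arrays called 9225 or 9566 probes. Leaving out a merged AML sample gave 0 calls under the 1% limit, and under the 5% limit gave 0 for 2 of the samples and 15017 for the third, the one that merges 3 arrays.

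**Figure D4:**
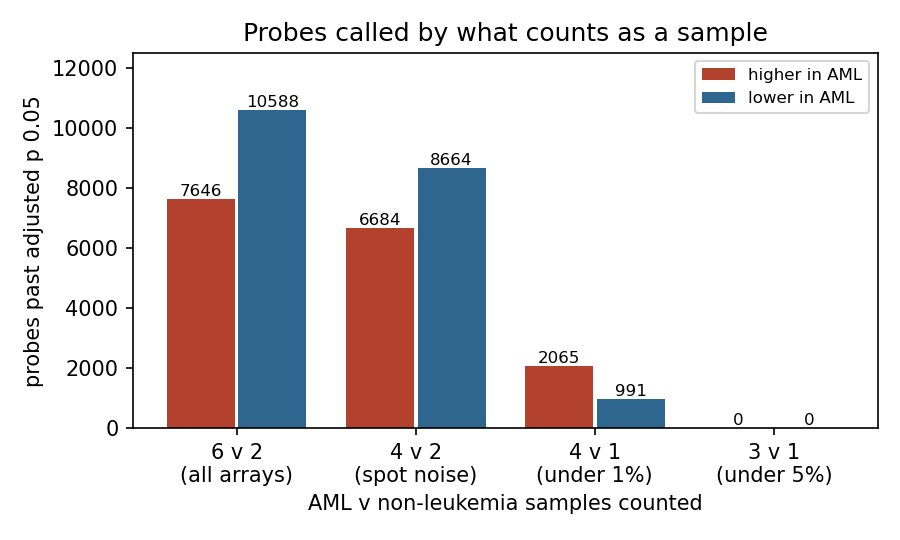
Number of probes past an adjusted p of 0.05 (vertical axis), higher (red) or lower (blue) in AML, by what was counted as a sample (horizontal axis). The counts go from 7646 and 10588 with all 8 arrays to 0 and 0 with arrays under the 5% limit merged.

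The differences in signal were large in many probes whatever their test result. Over the merged samples 6929 probes were at least 2-fold higher and 6285 at least 2-fold lower in AML. At least 8-fold differences were found for 686 and 694 probes. A total of 523 probes were well above background on all 6 AML arrays and on neither control array, and 750 on both control arrays and on no AML array. Over the 36702 probes with a value on every array, the AML and control arrays did not overlap for 64.9%, where chance gives 7.14% for 6 against 2 separate samples. That share of chance does not hold where arrays are near copies of each other.

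AML arrays had 31957 ± 1930 detected probes (SD, n = 3 merged samples) and the merged control sample had 32657. In the 3 pairs under 1%, the array on slide 1 had 4248, 4121 and 3570 more detected probes than its near copy on slide 2. The merged samples mix the slides unequally, and 1 AML sample lies on slide 1 alone. The SD and the comparison of merged samples therefore include that slide difference. Over 8 arrays the difference was -1110 probes, with an exact two-sided permutation p of 0.714 that ignores the slide and treats the arrays as separate. The control array had the highest count on both slides, and the difference was -1332 within slide 1 and -2452 within slide 2. With the slide as a term the difference was -1841, with an exact p of 0.133, the smallest that 15 assignments within slides allow. With so few arrays a difference is neither shown nor excluded.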

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

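All tests of explanations in this part were chosen after the results were seen.

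In DYNLL1, 1 of 6 AML arrays stood apart at a scaled log2 signal of 9.13, where the other AML arrays lay between 8.26 and 8.37. In H3-3A, 1 of 6 AML arrays stood at 10.13, against 9.37 to 9.49 in the others. In each case the gap to the nearest array exceeded Dixon's 95% critical share of the group's range. Both values come from the same array, so they are not independent cases. Over 23 measures, if these were independent, chance alone would give about 1.15 such cases, and the near copies among the AML arrays make a lone array easier to single out.

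Of 8 control probes written for rat and mouse transcripts, which no comparison used, 7 gave signal on all 8 arrays, and 3 of these were higher in every merged AML sample than in the control sample. The merged difference was 2.02 on the log2 scale for the rat GAPDH 5' probe, 0.78 for the rat PGK1 5' probe and 0.65 for the mouse PGK1 5' probe. The other detected probes gave -0.90 for the rat GAPDH 3' probe, -0.75 and -0.27 for the mouse GAPDH 5' and 3' probes, and -0.07 for the mouse PGK1 3' probe. The rat PGK1 3' probe was detected on 0 arrays.

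The first pattern is that arrays of one group differed by no more than the scanner's error. A shared slide is argued against, since 3 of 3 pairs under the 1% limit span both slides. Processing of the signals is argued against as well: the highest spread of raw pixel medians in those pairs was 0.056 on the log2 scale, below the lowest of the more distant AML pairs, 0.226. Over the 5 merged pairs as a set, one RNA placed on more than one array cannot be told apart from separate samples that resemble each other. The share of probes beyond the scanner's error cannot decide it, because that share defined the pairs. Against the noise between repeat spots the spread of 3 of the 5 merged pairs was larger, up to 2.26 times, but that noise leaves out what differs between arrays. In the 2 AML pairs under 1% the spread was 0.69 and 0.99 times that noise, no more than one RNA on both arrays would give. At most 0.018% of bright probes differed by more than 2-fold in those 2 pairs, against 0.28% to 13.9% in the more distant AML pairs. No biological explanation was tested.

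The second pattern is that named genes were mostly higher in AML. The slide is argued against, since both slides hold both groups and only 1 of 19 tested genes differed in sign between slides. Each slide 2 array is a near copy of a slide 1 array, so the likeness of the slides is not an independent repeat of the differences. A single scaling factor for all probes is argued against as the whole cause, since it would move the named genes and all probes alike. The median change of the named genes lay above that of all tested probes by 0.88 ± 0.14 on the log2 scale (SD, n = 3 merged AML samples), a distance that no such factor alters. Its 95% interval is 0.17 to 1.59 if the 1 control sample varies like the AML samples. A test on the span of the named genes' changes, tried first, did not decide it. A scaling that changes with the signal level stays open as part of the cause. Quantile normalization, which is such a scaling, was run as an alternative. Over samples merged under the 5% limit it lowered RACK1 from 1.07 to 0.72, GAPDH from 0.66 to 0.28 and ACTB from 0.04 to -0.33. PRMT1 went from 2.52 to 2.55, EIF3D from 2.09 to 2.28 and COX4I1 from 1.51 to 1.65. The other named genes moved either way. How much of the pattern such a scaling accounts for was not tested. RNA quality is confounded with the groups and cannot be told apart from a real difference, because the PGK1 end-probe gap differed by -0.47. The disease itself stays among the open explanations, untested.

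The third pattern is the smaller gap between 3' and 5' end probes in AML. The slide is argued against by the GAPDH difference of -0.37 within slide 2 and of -0.38 within slide 1. Here too the slide 2 arrays are near copies of slide 1 arrays, so the 2 values are not independent repeats. Saturated end probes are argued against, since 0 of the 3' spots of GAPDH and PGK1 were saturated on AML arrays. RNA integrity and a change of transcripts in the disease stay open, untested.

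For the 3056 calls with pairs under 1% merged, 1 of 5 ways to set a single sample apart, the real one, gave as many, and the highest of the others gave 0. With 5 splits no share under 0.05 can be reached. Every other split also leaves the control sample in the larger group. Arrays of AML and control differ at 58.5% to 70.0% of probes, which widens the spread there, so few calls are nearly forced. In the fit to all 8 arrays, setting a near-identical AML pair apart gave 299 calls, the highest of the other splits into 6 and 2, against 18207 for the real one over probes with a value on every array. Both control arrays stay among the 6 in that split, so the same limit holds.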

How the results depend on the processing

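The fits with merged arrays, with 1 slide and their variants were chosen after seeing the data. The count of called probes stayed within 1.5 times 18234 under every planned scaling, background correction, filter, variance model and slide block, between 14270 and 24965, but the calls rested on what counts as a sample. Arrays under the 5% limit merged gave 0 calls, and 0 under quantile or median scaling and 2 (0 higher, 2 lower) under normexp. Pairs under 1% merged gave 3056 (2065 higher, 991 lower), 3644 (2416, 1228) under quantile normalization, 3254 (2481, 773) under median scaling and 4208 (2272, 1936) under normexp. Of the 3056, 3054 were also called from 8 arrays. Merging by repeat-spot noise gave 15348 (6684 higher, 8664 lower) under both versions. Slide 1 alone gave 2952 (2023 higher, 929 lower) and slide 2 alone 0, with 4487 at an unadjusted p under 0.05. These fits had fewer samples, and each fit to 1 slide had 1 control array, assumed to vary like its AML arrays. Where the merged sample of 3 arrays is left out under the 5% limit, the AML samples that remain lie close to each other, so the spread there is small. Leaving out an array gave 9225 to 18145 calls (4637 to 7638 higher, 4588 to 10507 lower), the lowest without a control array, which leaves 1 control assumed to vary like the AML arrays. Leaving out 1 merged AML sample gave 0 calls under the 1% limit, and under the 5% limit 0, 0 and 15017 (7454 higher, 7563 lower).

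With the replicate number as a block limma called 0 probes (0 higher, 0 lower), with 11149 at an unadjusted p under 0.05. Only replicate numbers 1 and 2 occur in both groups, so the other AML arrays say nothing about the group there. Little is left to estimate the spread, so that count does not show that pairing removes the difference. Whether the numbers pair the samples could not be checked. Same-numbered arrays' deviations correlated at -0.03 and -0.04, but the 2 control arrays are near copies, so their deviations are mostly technical. A 2-fold change with unadjusted p under 0.05 gave 10248 probes, 4764 of them lower. The median probe's change was -0.19 and moved to -0.03 under median scaling and to -0.29 under the percentile of detected probes. ACTB, not called in the planned fit, turned to -0.30 under quantile normalization and gained a call, as did PFN1. ACTG1, GAPDH and RPLP1 lost their calls there. The cause was not tested. The difference in detected probes ranged from -2895 to 675 when arrays were left out. Of the 13 named genes called from 8 arrays, 11 were called with arrays merged by repeat-spot noise, 4 with pairs under 1% merged and 0 under the 5% limit. RPL10, not called from 8 arrays, was called with array weights (0.60) and with group-specific variances (0.48). Leaving out each of the 8 arrays in turn ended the call of DYNLL1 in 7 cases, of MTX1 in 5, of ACTG1 and PGK1 in 2 each, of RPLP1 in 1 and of the other named genes in 0. Gene lists, probe classes, fry, estimated correlations and averages over a gene's probes were not run, for want of gene names. Signal over background limits the dim probes, as 18541 were detected on no array.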
